A study of Homo sapiens with 40 samples.

How the data were processed

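Gene expression was measured on 40 one-colour Affymetrix arrays, each hybridised with biotin-labelled RNA from 1 culture of a human diffuse large B-cell lymphoma line. RNA was taken up in Trizol and cleaned on RNeasy columns, per the labels' protocols. The deposited table holds 54675 probe sets by 40 arrays, and every column name matched the GEO identifier of 1 sample. Per the submitters' processing notes the signals were made with MAS5, whose version is not given in the sources used here. MAS5 summarises the probes of a set on each array by itself and scales each array to a common target, so arrays are comparable as far as that scaling holds. The deposited values are log2 signals, per the labels and as the values themselves show: brought back to the linear scale, every array had a mean of 500 after trimming 2% of probe sets at each end. Detection calls were not used here. MAS5 values of dim probe sets scatter widely on the log scale, and the number of arrays limits the precision of every value.

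Values were kept as scaled by the authors, brought back to linear, and analysed as log2(signal + 17.72). This pseudocount is the median over the 40 arrays of each array's 25th percentile. Fold changes on that scale understate the change of dim genes. Gene symbols came from the platform annotation supplied with the data, which can be old. Of the probe sets, 41091 had 1 symbol, 1801 had several, 11721 had none and 62 were controls. The gene ID of 41037 single-symbol probe sets was found in a RefSeq gene table of assembly GRCh38.p14, used for names alone, and 0 symbols needed an update. A gene was represented by its single-symbol probe set with the highest mean over all arrays. It was tested if that probe set lay above the array's median on at least 2 arrays, which left 15211 of 19775 genes. Probe sets of 1 gene did not always move together: for FABP6, GBP2, SDR42E1, CCDC32, P4HA1 and DNAH6 the mean correlation between probe sets was below 0.

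Samples were grouped by cell line and treatment from the labels, giving 20 groups of 2 arrays. The titles call the 2 arrays of a group biological replicates, without saying how the cultures were separated. The p-values within a line therefore rest on the spread between such arrays, pooled over all 20 groups. For the response of each line, limma 3.58.1 in R 4.3.3 fitted all 40 arrays with 1 mean per group, moderated variances and an intensity trend. The fit left 20 residual degrees of freedom and 6.98 prior degrees of freedom, and GSK126 was compared with DMSO within each line. For statements across lines the line was the replicate. Each line gave 1 log2 fold change, and limma estimated the mean of the 7 mutant lines, the mean of the 3 wild type lines, their difference, and the slope on log10 of the growth IC50. The mean DMSO level per line was compared between genotypes in the same way. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors given as ± are standard errors of the fit unless SD is written.

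The number of changed genes was set against log10 of the growth IC50 by Pearson's r and Spearman's rho, with permutation p-values from 100000 resamples for 10 lines and exact ones for 7. Calls shared by several lines were compared with 1000 shuffles of each line's calls among genes of the same decile of mean expression. The labels' descriptions carry an R tag whose meaning is not given (R6 for Pfeiffer, KARPAS-422 and Toledo, R8 for SU-DHL-6 and OCI-LY-19, R7 for the other 5 lines), and it was treated as a possible batch.

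The gene lists numbered 30, with 677 genes, of which 558 genes were tested and 29 lists had at least 5 tested genes. They cover PRC2 and histone demethylases, PRC1 and CBX proteins, other chromatin modifiers, HOX genes, developmental transcription factors, cyclin-dependent kinase inhibitors, mitosis, DNA replication, MYC targets, p53 targets, apoptosis, germinal centre, plasma cell, memory and activated B cell genes, B cell identity, MHC class II, MHC class I, interferon-stimulated genes, NF-kB targets, chemokines and cytokines, adhesion and cytoskeleton, cholesterol synthesis, glycolysis and hypoxia, amino acid stress, and heat shock proteins. Markers of T and NK cells, myeloid cells, stromal and epithelial cells, and erythroid and endothelial cells were included as signs of other cell types. A further list, TXNIP and TNFRSF21, holds genes that the study followed, as known from its paper. Each list was tested with camera, which asks whether its genes moved relative to all other genes, with a preset correlation of 0.01 between genes and again with an estimated one. The fry test asks whether the genes of a list move one way on balance, without comparing them with other genes. Adjustment was over the lists within a comparison. A list count "adjusted over the list alone" repeats the Benjamini-Hochberg step over that list's genes.

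The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named for each line are the 3 risen and 3 fallen genes with the largest fold change among those called with both GSK126 arrays beyond both DMSO arrays. Across lines they are the 12 risen and 8 fallen genes called in the most lines. For the mutant mean the 12 largest each way are named, for the other responses 8 each way and under DMSO 10 each way, or as many as were called. Lists give 2 to 4 called members with the largest change, EZH2, TXNIP, TNFRSF21 and the PRC2 list always appear, and provisional symbols, open reading frames, pseudogenes, immunoglobulin segments, XIST and Y-linked genes were passed over. The alternatives were pseudocounts of 1 and 4 times the main value, no filter on dim genes, quantile normalization, the mean of all probe sets of a gene, a replicate block, each line fitted alone, a variance model without an intensity trend, a required 2-fold change, weights per line, the R tag as a block, and leaving out each array or line. Bringing all arrays to equal medians was added after seeing the data. The replicate numbers did not pair the arrays, so the main model has no replicate term.

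The scripts were tested on simulated data in which 200 of 15211 genes were changed. For 1 line, 40.3%, 71.6% and 90.9% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 10 wrong calls and 0 calls in the 9 unchanged lines. For the mutant mean 73.1%, 89.6% and 100% were recovered with 6 wrong calls, and for the wild type mean 31.3%, 61.2% and 95.5% with 10. For the difference of genotypes 14.9%, 52.2% and 84.8% were recovered with 7 wrong calls, and for the slope 41.8%, 85.1% and 98.5% with 9. For the DMSO comparison 0%, 10.4% and 54.5% were recovered with 2 wrong calls. Camera called the shifted list and 0 others, and was not tested on correlated genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.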

Results

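Expression was measured in 10 established lines of diffuse large B-cell lymphoma, an aggressive tumour of mature B cells, after treatment with GSK126. This small molecule inhibits EZH2, the enzyme of Polycomb repressive complex 2 (PRC2) that methylates histones at repressed genes. Pfeiffer, WSU-DLCL2, KARPAS-422, SU-DHL-10, SU-DHL-6, SU-DHL-4 and DB carry mutant EZH2, and HT, Toledo and OCI-LY-19 are wild type for it. Cells received 500 nM GSK126 or 0.1% DMSO for 72 h, with 2 arrays per line and treatment, 40 in all. The growth IC50 in the labels, the dose that reduces proliferation by a set amount, was 28 nM in Pfeiffer, 134 nM in WSU-DLCL2, 232 nM in KARPAS-422, 448 nM in SU-DHL-10 and 516 nM in HT. It was 582 nM in SU-DHL-6, 861 nM in DB, 1019 nM in OCI-LY-19, 4828 nM in SU-DHL-4 and 13786 nM in Toledo. Every array correlated best with another array of its own line. Replicate arrays correlated at 0.938 to 0.959, arrays of 1 line under different treatments at 0.932 to 0.957 and arrays of different lines at 0.832 to 0.930.

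The first question was which genes responded to the inhibitor in each line. KARPAS-422 had the most called genes, with 2355 genes risen and 2039 fallen of 15211 tested (limma, Benjamini-Hochberg adjusted). WSU-DLCL2 followed with 2118 risen and 1928 fallen, Pfeiffer with 2228 and 1510, SU-DHL-10 with 1673 and 1089, SU-DHL-6 with 1129 and 541, and HT with 960 and 457. The response was narrow in DB (381 risen, 94 fallen), SU-DHL-4 (326 and 69), OCI-LY-19 (299 and 67) and Toledo (21 and 4). WSU-DLCL2 came first instead with quantile normalization (3996 genes against 3970) and with each line fitted alone (4025 against 3779). Large rises outnumbered large falls: 842 genes rose and 113 fell at least 2-fold in KARPAS-422, 503 and 73 in Pfeiffer, and 60 and 5 in SU-DHL-4. Risen genes outnumbered fallen ones in 10 of 10 lines (exact two-sided sign test, p = 0.00195), but this balance depended on how arrays were scaled.

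Bringing arrays to equal medians was an alternative chosen after seeing the data. The median of all genes then shifted by -0.14 in Pfeiffer, -0.22 in WSU-DLCL2, -0.15 in KARPAS-422, -0.23 in SU-DHL-10, -0.17 in SU-DHL-6 and -0.14 in Toledo. It shifted by at most 0.07 in size in the other lines. Fallen genes then outnumbered risen ones in Pfeiffer (969 risen, 2201 fallen), WSU-DLCL2 (827, 3696), KARPAS-422 (1545, 3298), SU-DHL-10 (777, 3320) and SU-DHL-6 (572, 1897). Toledo then had 9 risen and 8 fallen, against 12 and 8 with quantile normalization and 8 and 4 with the mean of all probe sets. HT had 506 risen and 342 fallen, DB 339 and 37, OCI-LY-19 127 and 37, and SU-DHL-4 173 and 18. The direction of no gene named for a line, the mutant mean, the growth IC50 or the DMSO levels turned under either scaling. Leaving out 1 array moved some counts by over 1.5 times. HT then had 772 to 860 called genes in place of 1417, and DB 268 to 313 in place of 475, whichever array was left out. SU-DHL-6 had 921 without DMSO replicate 1 and 1091 without GSK126 replicate 2, in place of 1670. OCI-LY-19 had 237 without DMSO replicate 2, 205 without GSK126 replicate 1 and 196 without GSK126 replicate 2, in place of 366. SU-DHL-4 had 179, 247 and 171 without the same 3 arrays, in place of 395, and Toledo had 38 without DMSO replicate 1 and 48 without DMSO replicate 2, in place of 25.

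**Figure D1:**
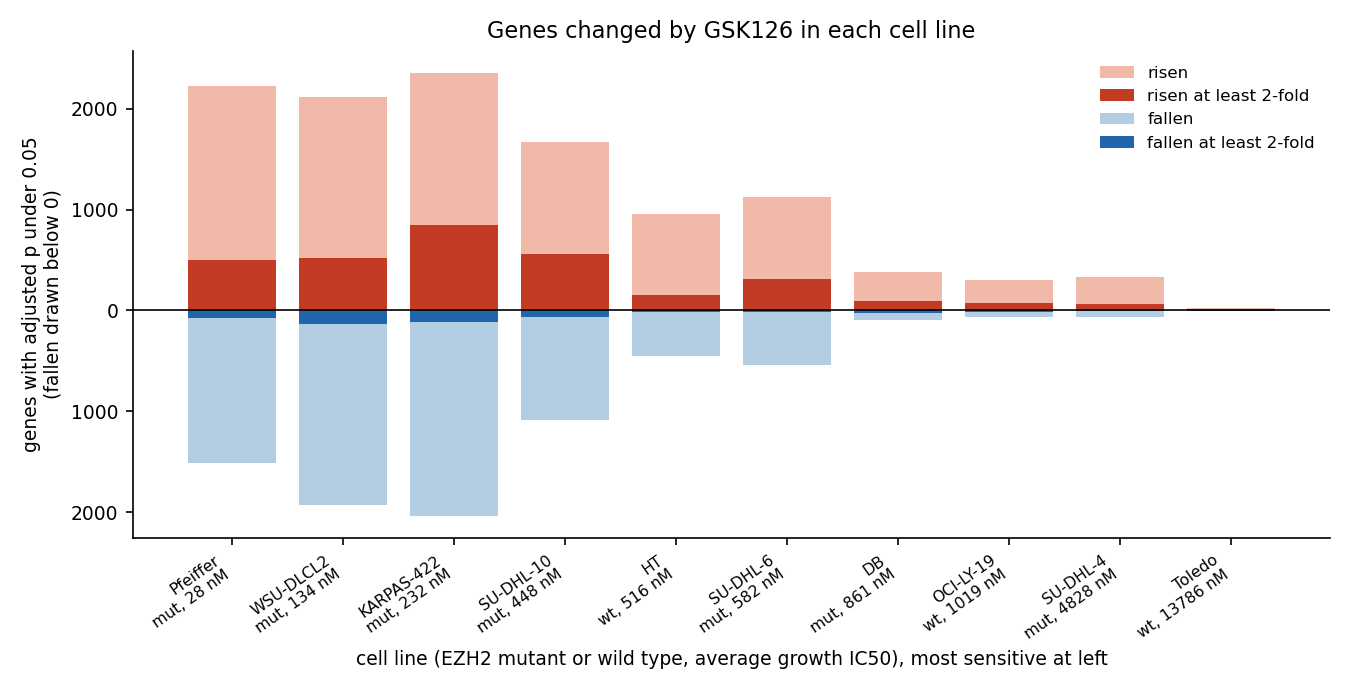
Number of genes risen (up) and fallen (down) with GSK126 in each line, ordered by growth IC50, as bars, with the part changed at least 2-fold drawn darker. KARPAS-422 has 2355 risen and 2039 fallen genes and Toledo 21 and 4, and with arrays at equal medians fallen genes outnumber risen ones in Pfeiffer, WSU-DLCL2, KARPAS-422, SU-DHL-10 and SU-DHL-6.

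EZH2 mRNA itself, the target of the drug, fell in Pfeiffer by a log2 fold change of -0.65 ± 0.06, adjusted p = 6.63e-10. Smaller falls were measured in WSU-DLCL2 (-0.35 ± 0.06), SU-DHL-10 (-0.30 ± 0.06), SU-DHL-6 (-0.24 ± 0.06) and HT (-0.19 ± 0.06). It did not pass the test in KARPAS-422 (-0.13 ± 0.06, adjusted p = 0.0887), DB, OCI-LY-19, SU-DHL-4 or Toledo, where it lay between -0.06 and 0.07. With arrays at equal medians EZH2 passed the test in KARPAS-422 (-0.30, adjusted p = 0.0114) and not in HT (-0.26, adjusted p = 0.0965). Of the PRC2 list, EED fell in 6 lines, most in WSU-DLCL2 (-0.35 ± 0.05). MTF2 fell in WSU-DLCL2 (-0.50 ± 0.06), SU-DHL-10 (-0.38 ± 0.06), HT and SU-DHL-6. SUZ12 fell in Pfeiffer (-0.33 ± 0.07) and KARPAS-422 (-0.20 ± 0.07). EPOP, a cofactor of PRC2, rose in 6 lines, with 0.78 ± 0.11 in SU-DHL-10 and 0.73 ± 0.11 in KARPAS-422. JARID2, another cofactor, rose in KARPAS-422 (1.11 ± 0.13), Pfeiffer (0.60 ± 0.13) and WSU-DLCL2 (0.40 ± 0.13). The demethylase gene KDM6B fell in WSU-DLCL2 (-0.65 ± 0.13) and HT (-0.41 ± 0.13). EZH1 rose in Pfeiffer (0.33 ± 0.10) and KARPAS-422 (0.38 ± 0.10). The list as a whole was called in SU-DHL-10 alone (median -0.17, camera adjusted p = 0.0202, adjusted p = 0.0739 with an estimated correlation), with 2 of 14 genes risen and 4 fallen (2 risen and 7 fallen adjusted over the list alone). TXNIP, an inhibitor of thioredoxin, rose in 7 lines, from 2.39 ± 0.11 in Pfeiffer to 0.41 ± 0.11 in DB. It lay between -0.01 and 0.23 without passing the test in OCI-LY-19, SU-DHL-4 and Toledo. TNFRSF21, a death receptor gene, rose in KARPAS-422 (2.68 ± 0.35) and Pfeiffer (2.39 ± 0.35). The study followed TXNIP and TNFRSF21 on these samples, so their direction is not independent evidence.

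In KARPAS-422 the interferon-stimulated genes rose together. Of 37 tested, 33 rose and 0 fell (33 risen adjusted over the list alone, median 2.64, camera adjusted p = 1.23e-33). They were led by IFI44L (5.78 ± 0.32, adjusted p = 3.05e-14), RSAD2, which encodes the antiviral protein viperin (5.18 ± 0.43), IFI27 (4.96 ± 0.45) and IFI16, a DNA sensor (4.83 ± 0.06). RTP4, also induced by interferon but outside the list, rose by 5.53 ± 0.38. MHC class I and antigen processing genes rose too, with 14 of 17 risen and 1 fallen (15 risen and 2 fallen adjusted over the list alone, median 1.01, camera adjusted p = 1.54e-14). Among them were HLA-G (1.93 ± 0.16), the transactivator NLRC5 (1.91 ± 0.29) and HLA-B (1.86 ± 0.09). Markers of T and NK, myeloid, stromal, epithelial, erythroid and endothelial cells were measured beside them. Of 41 tested, 3 rose (LCK 0.83, SPARC 1.33, ACTA2 1.04) and 2 fell. The stromal and epithelial markers had a median of 0.69 and moved up on balance by fry (adjusted p = 0.000163), without a camera call (0.321). Among B cell genes TCL1A, a germinal centre gene and AKT coactivator, rose by 3.07 ± 0.12, and JCHAIN, which joins secreted antibodies, by 4.66 ± 0.28. The germinal centre list had 9 of 22 risen and 1 fallen (10 risen and 1 fallen adjusted over the list alone, median 0.27, camera adjusted p = 0.00424). The plasma cell list had 10 risen and 6 fallen of 22 (11 risen and 7 fallen adjusted over the list alone, median 0.33, camera adjusted p = 0.0458, adjusted p = 0.103 with an estimated correlation). The memory and activated list had 7 risen and 3 fallen of 24 (8 risen and 3 fallen adjusted over the list alone, median 0.27, camera adjusted p = 0.0483, adjusted p = 0.103 with an estimated correlation). In that last list AIM2 (4.16 ± 0.24) and BACH2 (3.51 ± 0.16) rose while the early response genes EGR3 (-1.97 ± 0.43) and EGR1 (-1.73 ± 0.19) fell.

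The largest falls in KARPAS-422 were those of LTA, which encodes lymphotoxin alpha (-2.90 ± 0.21, adjusted p = 1.39e-11), CHAC1, a glutathione-degrading enzyme of the amino acid stress response (-2.72 ± 0.33), and the early response gene FOS (-2.47 ± 0.34). Of 29 DNA replication genes 28 fell (28 fallen adjusted over the list alone, median -0.56, camera adjusted p = 5.08e-23), GINS2 at -0.85 ± 0.06. Of 30 mitotic genes 22 fell (22 fallen adjusted over the list alone, median -0.32, camera adjusted p = 9.4e-12). MYC targets fell in 13 of 18 cases (13 fallen adjusted over the list alone, median -0.25, camera adjusted p = 1.16e-05), with CAD, an enzyme of pyrimidine synthesis, at -0.67 ± 0.10. Glycolysis and hypoxia genes had 14 of 25 fallen and 1 risen (2 risen and 15 fallen adjusted over the list alone, median -0.24, camera adjusted p = 0.00105), VEGFA among them (-1.66 ± 0.15). Amino acid stress genes had 10 fallen and 3 risen of 20 (3 risen and 10 fallen adjusted over the list alone, median -0.25, camera adjusted p = 0.00151). Adhesion and cytoskeleton genes had 9 of 30 risen and 3 fallen (9 risen and 3 fallen adjusted over the list alone, median 0.35, camera adjusted p = 0.0267), with S100A4 at 2.83 ± 0.16. Cholesterol synthesis genes had 9 of 22 fallen and 2 risen (2 risen and 9 fallen adjusted over the list alone, median -0.21, camera adjusted p = 0.0066, adjusted p = 0.0597 with an estimated correlation). With quantile normalization the calls of the memory (adjusted p = 0.102) and cholesterol (0.0698) lists were lost, and with a pseudocount of 1 that of the plasma cell list (0.0775).

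Pfeiffer, the line with the lowest growth IC50, showed the most uniform fall of cell cycle genes. All 29 DNA replication genes fell (29 fallen adjusted over the list alone, median -0.67, camera adjusted p = 6.77e-37), with CDT1 (-1.10 ± 0.14) and CDC45 (-1.10 ± 0.13), which load and start the replicative helicase, at the front. Of 30 mitotic genes 29 fell (29 fallen adjusted over the list alone, median -0.62, camera adjusted p = 2.26e-35), CCNA2 at -0.97 ± 0.06 and AURKB at -0.88 ± 0.08. Chromatin modifier genes had 8 of 20 fallen and 1 risen (1 risen and 8 fallen adjusted over the list alone, median -0.16, camera adjusted p = 0.00349), with NSD2 at -0.83 ± 0.09 and DNMT3B at -0.83 ± 0.20. MYC targets had 7 of 18 fallen and 1 risen (3 risen and 7 fallen adjusted over the list alone, median -0.13, camera adjusted p = 0.00938, adjusted p = 0.145 with an estimated correlation). In cholesterol and fatty acid synthesis 10 of 22 fell and 1 rose (1 risen and 10 fallen adjusted over the list alone, median -0.27, camera adjusted p = 0.000394), HMGCS1 at -1.99 ± 0.27. The genes with the largest change were TENT5C, a poly(A) polymerase gene (3.74 ± 0.36, adjusted p = 5.58e-09), RCSD1 (3.62 ± 0.10) and the cannabinoid receptor gene CNR1 (3.40 ± 0.18) among the risen genes. Among the fallen genes they were PNMA8A (-2.39 ± 0.32), STEEP1 (-2.24 ± 0.43) and HINT3 (-2.22 ± 0.19). STEEP1 lost its call when the line was fitted alone.

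B cell programmes rose in Pfeiffer. PRDM1, the master regulator of plasma cells, rose by 2.77 ± 0.36. The plasma cell list had 9 of 22 risen and 1 fallen (9 risen and 1 fallen adjusted over the list alone, median 0.26, camera adjusted p = 0.00269). Germinal centre genes had 10 of 22 risen (10 risen adjusted over the list alone, median 0.23, camera adjusted p = 0.00118), with LMO2 at 1.90 ± 0.16. Of 24 memory and activated genes 10 rose (11 risen adjusted over the list alone, median 0.45, camera adjusted p = 0.00269), with the chemokine receptor gene CCR7 at 2.40 ± 0.37. Of 30 B cell identity genes 14 rose and 1 fell (16 risen and 2 fallen adjusted over the list alone, median 0.21, camera adjusted p = 0.00269), with EBF1 at 1.45 ± 0.10. MHC class II had 10 of 15 risen and 1 fallen (11 risen and 2 fallen adjusted over the list alone, median 0.36, camera adjusted p = 0.000394), HLA-DOB by 1.14 ± 0.13. MHC class I had 10 of 17 risen (11 risen adjusted over the list alone, median 0.33, camera adjusted p = 0.000394), NLRC5 by 0.94 ± 0.29. Adhesion genes had 12 of 30 risen and 1 fallen (13 risen and 1 fallen adjusted over the list alone, median 0.54, camera adjusted p = 0.000845), ITGB5 by 1.54 ± 0.43. Chemokine and cytokine genes had 9 of 31 risen (9 risen adjusted over the list alone, median 0.37, camera adjusted p = 0.00349), CXCL13 by 2.32 ± 0.34. Interferon-stimulated genes had 10 of 37 risen (10 risen adjusted over the list alone, median 0.29, camera adjusted p = 0.0101, adjusted p = 0.0743 with an estimated correlation). Of 20 NF-kB targets 8 rose (9 risen adjusted over the list alone, median 0.23, camera adjusted p = 0.0293, adjusted p = 0.118 with an estimated correlation), TNFAIP3 by 1.12 ± 0.16. Of 22 apoptosis regulators 10 rose and 1 fell (10 risen and 1 fallen adjusted over the list alone, median 0.25, camera adjusted p = 0.0462, adjusted p = 0.0519 with an estimated correlation), BMF by 1.02 ± 0.21. With quantile normalization and with arrays at equal medians the calls of apoptosis (adjusted p = 0.0561 and 0.173) and NF-kB (0.0554 and 0.0613) were lost.

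WSU-DLCL2 showed a rise of B cell identity genes and a fall of NF-kB targets. TCL1A rose by 4.88 ± 0.12, adjusted p = 3.08e-21, followed by the membrane-curving protein gene BIN1 (3.86 ± 0.35) and CDHR3 (3.53 ± 0.31). Of 30 B cell identity genes 16 rose and 2 fell (18 risen and 2 fallen adjusted over the list alone, median 0.34, camera adjusted p = 1.16e-07), CD24 by 2.60 ± 0.09 and FCRL3 by 2.16 ± 0.10. Of 20 NF-kB targets 13 fell and 1 rose (1 risen and 13 fallen adjusted over the list alone, median -0.68, camera adjusted p = 1.57e-07), LTA at -2.53 ± 0.21, the survival gene BCL2A1 at -2.02 ± 0.21 and TNFAIP3 at -1.24 ± 0.16. The activation marker CD69 (-3.47 ± 0.40), LINC00158 (-3.07 ± 0.44) and INHBE (-3.04 ± 0.30) fell most. Cholesterol synthesis genes rose, 14 of 22 (16 risen adjusted over the list alone, median 0.36, camera adjusted p = 3.78e-09), HMGCS1 by 1.48 ± 0.27 and MSMO1 by 1.01 ± 0.08. Amino acid stress genes fell, 10 of 20 with 2 risen (2 risen and 11 fallen adjusted over the list alone, median -0.42, camera adjusted p = 8.55e-06), the cystine transporter gene SLC7A11 at -2.04 ± 0.17 and DDIT3 at -1.69 ± 0.16.

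DNA replication genes in WSU-DLCL2 had 19 of 29 fallen (20 fallen adjusted over the list alone, median -0.31, camera adjusted p = 2.34e-10), CDC45 at -1.12 ± 0.13. Mitotic genes had 14 of 30 fallen and 1 risen (2 risen and 17 fallen adjusted over the list alone, median -0.17, camera adjusted p = 4.53e-05). MHC class II had 7 of 15 risen and 1 fallen (8 risen and 1 fallen adjusted over the list alone, median 0.29, camera adjusted p = 0.00173), with its transactivator CIITA at 1.18 ± 0.24. Adhesion genes had 9 of 30 risen and 1 fallen (9 risen and 1 fallen adjusted over the list alone, median 0.19, camera adjusted p = 0.0324), S100A4 by 2.75 ± 0.16. They kept their call with arrays at equal medians although their median then was -0.04. Of 17 MHC class I genes 4 rose (4 risen adjusted over the list alone, median 0.17, camera adjusted p = 0.0359, adjusted p = 0.155 with an estimated correlation). Of 9 heat shock proteins 4 rose (4 risen adjusted over the list alone, median 0.15, camera adjusted p = 0.00206, adjusted p = 0.0675 with an estimated correlation). With arrays at equal medians these medians turned to -0.08 and -0.10 and the calls were lost (adjusted p = 0.627 and 0.170).

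SU-DHL-10 gained SRGN, which encodes a granule proteoglycan (4.21 ± 0.13, adjusted p = 7.02e-19), the bile acid-binding protein gene FABP6 (3.96 ± 0.19) and ZNF362 (3.83 ± 0.14). It lost LRRTM4-AS1 (-2.22 ± 0.27), INHBE (-2.16 ± 0.30) and CHAC1 (-2.14 ± 0.33). Amino acid stress genes had 9 of 20 fallen and 4 risen (4 risen and 10 fallen adjusted over the list alone, median -0.26, camera adjusted p = 0.00893, adjusted p = 0.133 with an estimated correlation). Glycolysis genes had 9 of 25 fallen and 2 risen (2 risen and 9 fallen adjusted over the list alone, median -0.15, camera adjusted p = 0.00734, adjusted p = 0.133 with an estimated correlation). NF-kB targets had 5 of 20 fallen and 1 risen (1 risen and 5 fallen adjusted over the list alone, median -0.12, camera adjusted p = 0.0292, adjusted p = 0.143 with an estimated correlation), with LTA at -1.12 ± 0.21 and LTB at -0.99 ± 0.09. DNA replication genes had 8 of 29 fallen (8 fallen adjusted over the list alone, median -0.11, camera adjusted p = 0.000888, adjusted p = 0.0739 with an estimated correlation), E2F1 at -0.72 ± 0.12. Mitotic genes had 9 of 30 fallen and 2 risen (2 risen and 10 fallen adjusted over the list alone, median -0.11, camera adjusted p = 0.00243, adjusted p = 0.0739 with an estimated correlation). Of 17 MHC class I genes 6 rose (8 risen and 1 fallen adjusted over the list alone, median 0.16, camera adjusted p = 0.0367, adjusted p = 0.182 with an estimated correlation). Of 9 heat shock proteins 4 rose (4 risen adjusted over the list alone, median 0.04, camera adjusted p = 0.00893, adjusted p = 0.133 with an estimated correlation), BAG3 by 1.56 ± 0.09. With arrays at equal medians these medians turned to -0.09 and -0.22 and the calls were lost (adjusted p = 0.608 and 0.194). Quantile normalization ended the calls of the PRC2, mitosis and NF-kB lists (adjusted p = 0.0552 for each), and a pseudocount of 1 that of NF-kB (0.0579).

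SU-DHL-6 raised ANXA4, an annexin gene (2.71 ± 0.25, adjusted p = 1.11e-08), SMAD1, a mediator of BMP signalling (2.65 ± 0.32), and TMEM200A (2.55 ± 0.31). CHRNA6 (-1.73 ± 0.30), GBP2 (-1.64 ± 0.42) and the resistin gene RETN (-1.51 ± 0.44) fell. DNA replication genes had 6 of 29 fallen (13 fallen adjusted over the list alone, median -0.20, camera adjusted p = 1.42e-10), POLE at -0.57 ± 0.09. MHC class I had 7 of 17 risen and 1 fallen (10 risen and 1 fallen adjusted over the list alone, median 0.22, camera adjusted p = 0.00606, adjusted p = 0.112 with an estimated correlation), the immunoproteasome gene PSMB9 by 1.05 ± 0.07. MHC class II had 3 of 15 risen (4 risen adjusted over the list alone, median 0.23, camera adjusted p = 0.00706, adjusted p = 0.0938 with an estimated correlation), HLA-DOA by 0.69 ± 0.09. MYC targets had 3 of 18 fallen (4 fallen adjusted over the list alone, median -0.07, camera adjusted p = 0.00606, adjusted p = 0.163 with an estimated correlation). Cholesterol synthesis genes had 3 of 22 fallen and 1 risen (1 risen and 3 fallen adjusted over the list alone, median -0.11, camera adjusted p = 0.0367, adjusted p = 0.163 with an estimated correlation). Both MHC calls were lost with arrays at equal medians (adjusted p = 0.226 for each) and the MYC and cholesterol calls with quantile normalization (0.235 and 0.437). Fitted alone, the line lost the call of RETN.

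HT, a wild type line, lost CHAC1 (-2.45 ± 0.33, adjusted p = 6.21e-06), LINC01723 (-1.90 ± 0.46) and the collagen gene COL12A1 (-1.80 ± 0.55). It gained LSP1, a leukocyte actin-binding protein gene (2.20 ± 0.23), the semaphorin receptor gene PLXNA1 (2.10 ± 0.30) and GALNT14 (2.05 ± 0.24). Of 29 DNA replication genes 14 fell (1 risen and 26 fallen adjusted over the list alone, median -0.30, camera adjusted p = 7.42e-21), CDC6 at -0.68 ± 0.07. Of 30 mitotic genes 7 fell (10 fallen adjusted over the list alone, median -0.16, camera adjusted p = 1.56e-09). Amino acid stress genes had 8 of 20 fallen (10 fallen adjusted over the list alone, median -0.33, camera adjusted p = 7.76e-08), the serine synthesis gene PSAT1 at -0.99 ± 0.09. NF-kB targets had 5 of 20 fallen (1 risen and 6 fallen adjusted over the list alone, median -0.24, camera adjusted p = 0.000541), LTA at -1.17 ± 0.21 and TNF at -0.89 ± 0.22. Interferon-stimulated genes had 7 of 37 risen and 1 fallen (10 risen and 1 fallen adjusted over the list alone, median 0.27, camera adjusted p = 0.0436, adjusted p = 0.181 with an estimated correlation), IFITM3 by 1.28 ± 0.27 and IFIT1 by 1.28 ± 0.29. Apoptosis regulators had 1 of 22 fallen, PMAIP1 (-0.80 ± 0.11) (1 fallen adjusted over the list alone, median -0.12, camera adjusted p = 0.0372). Quantile normalization ended the calls of the last 2 lists (adjusted p = 0.0878 and 0.0767), and a pseudocount of 1 that of the interferon list (0.0667). COL12A1 lost its call with the mean of all probe sets and without an intensity trend, and LINC01723 when the line was fitted alone.

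DB, a mutant line with a narrow response, raised antigen presentation genes. Of 15 MHC class II genes 6 rose (7 risen adjusted over the list alone, median 0.31, camera adjusted p = 2.1e-09), HLA-DPB1 by 1.05 ± 0.12 and HLA-DRA by 0.86 ± 0.10. Of 17 MHC class I genes 5 rose (7 risen adjusted over the list alone, median 0.15, camera adjusted p = 1.19e-11), NLRC5 by 1.44 ± 0.29 and HLA-B by 1.13 ± 0.09. JCHAIN had the largest rise (3.68 ± 0.28, adjusted p = 4.73e-10), ahead of SRGN (2.30 ± 0.13) and GAL3ST1 (2.27 ± 0.34). The plasma cell list had 3 of 22 risen (8 risen and 1 fallen adjusted over the list alone, median 0.18, camera adjusted p = 4.79e-05). SPATA4 (-2.01 ± 0.44), MYL3 (-1.76 ± 0.46) and NTS, the neurotensin gene (-1.76 ± 0.50, adjusted p = 0.049), fell most. PRC1 genes had 2 of 16 risen (3 risen adjusted over the list alone, median 0.07, camera adjusted p = 0.0465, adjusted p = 0.0766 with an estimated correlation), CBX7 by 0.79 ± 0.19. Of 24 memory and activated genes 4 rose (7 risen adjusted over the list alone, median 0.05, camera adjusted p = 0.0484, adjusted p = 0.127 with an estimated correlation), AIM2 by 1.70 ± 0.24. Of 18 MYC targets 1 rose (1 risen adjusted over the list alone, median 0.08, camera adjusted p = 0.009, adjusted p = 0.176 with an estimated correlation). Of 20 NF-kB targets 1 rose and 2 fell (1 risen and 4 fallen adjusted over the list alone, median -0.16, camera adjusted p = 0.0165, adjusted p = 0.127 with an estimated correlation). Cholesterol synthesis genes had 1 of 22 fallen (2 fallen adjusted over the list alone, median -0.09, camera adjusted p = 0.00142). DNA replication genes had 1 of 29 fallen (2 fallen adjusted over the list alone, median -0.04, camera adjusted p = 0.0487, adjusted p = 0.262 with an estimated correlation). With arrays at equal medians their median was 0.00 and the call was lost (adjusted p = 0.257). The memory list lost its call with arrays at equal medians (0.0628) and with a pseudocount of 1 (0.101), MYC with quantile normalization (0.247). NTS lost its call with 7 of the alternatives, arrays at equal medians among them.

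OCI-LY-19, a wild type line, also raised MHC class II, with 7 of 15 genes risen (8 risen adjusted over the list alone, median 0.55, camera adjusted p = 4.1e-17), HLA-DRA by 1.49 ± 0.10, adjusted p = 2.26e-11 and HLA-DRB1 by 1.30 ± 0.08. Of 17 MHC class I genes 2 rose (8 risen adjusted over the list alone, median 0.19, camera adjusted p = 4.46e-05). Of 22 germinal centre genes 3 rose (5 risen adjusted over the list alone, median 0.16, camera adjusted p = 0.00629), BCL6 by 0.42 ± 0.08. Of 30 B cell identity genes 6 rose (10 risen adjusted over the list alone, median 0.06, camera adjusted p = 0.00112), the transcription factor gene SPIB by 1.31 ± 0.08 and MS4A1 by 0.88 ± 0.08. The last list was still called with arrays at equal medians, but its median then turned to -0.01. TMEM170B (2.68 ± 0.31), IGFBP4 (2.05 ± 0.28) and ANXA13 (1.86 ± 0.41) rose most. The myoglobin gene MB (-1.73 ± 0.42), TLR9, a receptor for unmethylated DNA (-1.69 ± 0.17), and ARHGEF10 (-1.52 ± 0.33) fell most. Mitotic (median -0.06, camera adjusted p = 0.00121) and DNA replication (median -0.07, camera adjusted p = 0.00124, adjusted p = 0.066 with an estimated correlation) genes shifted as lists. They had 0 members called in either over all genes and 0 adjusted over the list alone. Glycolysis genes had 1 of 25 fallen (3 fallen adjusted over the list alone, median -0.10, camera adjusted p = 0.0013, adjusted p = 0.066 with an estimated correlation). Fitted alone, the line lost the calls of ANXA13, MB, TLR9 and ARHGEF10, and ARHGEF10 lost it with the mean of all probe sets too.

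SU-DHL-4, the least sensitive mutant line, raised SRGN (2.24 ± 0.13, adjusted p = 7.3e-12), ANXA4 (2.06 ± 0.25) and EFCAB12 (1.96 ± 0.36). It lost LRRTM4-AS1 (-1.47 ± 0.27), POM121L12 (-1.39 ± 0.27) and ARMCX2 (-1.36 ± 0.36). DNA replication genes had 2 of 29 fallen (8 fallen adjusted over the list alone, median -0.16, camera adjusted p = 2.59e-11), TK1 at -0.32 ± 0.07 and GINS2 at -0.31 ± 0.06. Of 30 mitotic genes 0 passed the test (6 fallen adjusted over the list alone, median -0.14, camera adjusted p = 8.03e-09). MHC class I had 3 of 17 risen (4 risen adjusted over the list alone, median 0.10, camera adjusted p = 0.00082, adjusted p = 0.0665 with an estimated correlation), CALR by 0.64 ± 0.07. Fitted alone, the line lost the calls of ANXA4, POM121L12 and ARMCX2, and a pseudocount of 1 ended those of EFCAB12 and LRRTM4-AS1. In Toledo, the least sensitive line, SDR42E1 (1.72 ± 0.30, adjusted p = 0.00799), LPAR2, a lysophosphatidic acid receptor gene (1.65 ± 0.28), and GAREM2 (1.56 ± 0.32) rose. NABP1 (-1.24 ± 0.25), SH3BP2 (-1.08 ± 0.23) and CCDC32 (-0.66 ± 0.10) fell. Its only called list was cholesterol synthesis (median -0.03, camera adjusted p = 0.00805, adjusted p = 0.222 with an estimated correlation), with 0 of 22 genes called over all genes and 3 fallen adjusted over the list alone. Fitted alone, limma called 0 genes in Toledo, against 25 in the 40-array model and 1018 at an unadjusted p under 0.05. Each of these 6 genes lost its call there and with the mean of all probe sets, where CCDC32 stood at 0.02.

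Camera called 16 lists in Pfeiffer, 10 in WSU-DLCL2, 12 in KARPAS-422, 8 in SU-DHL-10, 6 in HT, 5 in SU-DHL-6, 9 in DB, 7 in OCI-LY-19, 3 in SU-DHL-4 and 1 in Toledo. With an estimated correlation it called 12, 8, 9, 0, 5, 1, 4, 5, 2 and 0 of them in the same order. In these lines fry found movement one way on balance for every called list except DNA replication in DB (adjusted p = 0.0841) and cholesterol synthesis in Toledo (adjusted p = 0.206). HOX genes, developmental transcription factors, cyclin-dependent kinase inhibitors and p53 targets were called by camera in none of the 10 lines. By fry HOX genes moved up in Pfeiffer (adjusted p = 0.0379), KARPAS-422 (0.00222), SU-DHL-10 (0.00557), HT (0.012) and SU-DHL-6 (0.0433). Of 19 HOX genes 5 rose in KARPAS-422, 2 each in Pfeiffer, WSU-DLCL2 and SU-DHL-10, 1 each in HT, SU-DHL-6 and DB, and 0 fell in any line. With quantile normalization 4 HOX genes rose in KARPAS-422, 2 in Pfeiffer, 1 each in SU-DHL-10, HT, SU-DHL-6 and DB and 0 in WSU-DLCL2. Under it 1 HOX gene fell in each of Pfeiffer and KARPAS-422. With arrays at equal medians 4 rose in KARPAS-422, 1 each in Pfeiffer and DB, and 0 in any other line. In that setting 1 fell in each of KARPAS-422 and SU-DHL-6. The fry test was not repeated under either scaling. T and NK cell (15 tested), myeloid (10), stromal and epithelial (10) and erythroid and endothelial (6) markers were called in none of the lines either, with at most 2 called members per list and line. By fry, stromal and epithelial markers moved up in KARPAS-422, Pfeiffer (adjusted p = 0.0158) and SU-DHL-10 (0.0426), and myeloid markers up in SU-DHL-10 (0.0391) and down in KARPAS-422 (0.00935).

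**Figure D2:**
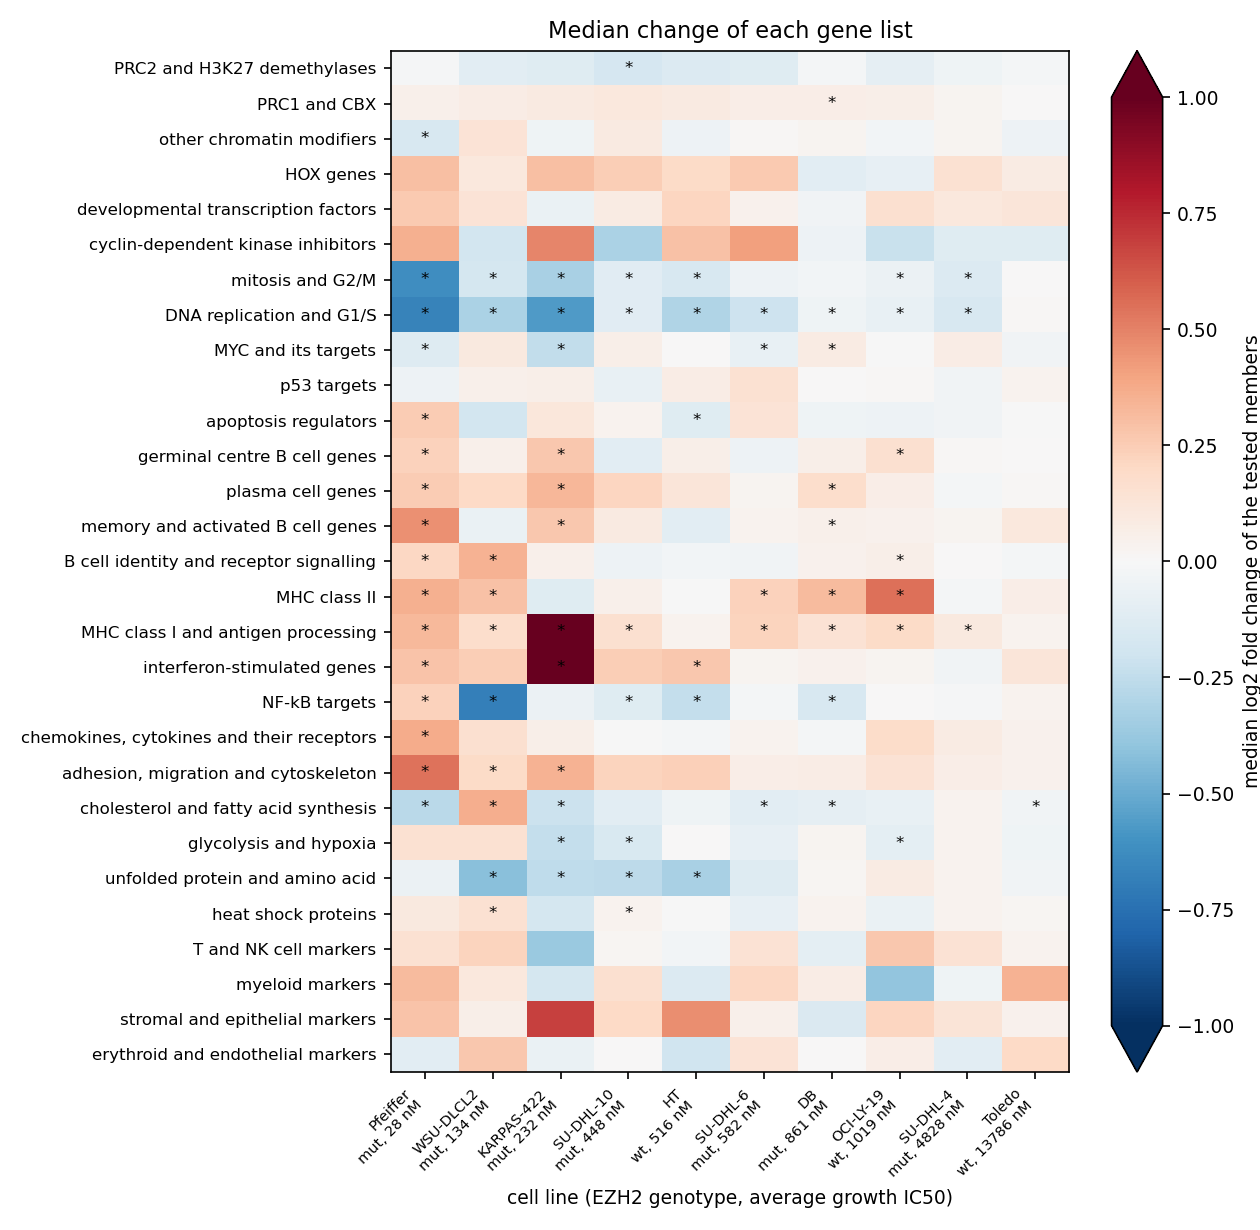
Median log2 fold change (colour, from -1 to 1) of each gene list with at least 5 tested genes in each line, with a star where camera called the list. DNA replication is at -0.67 in Pfeiffer and interferon-stimulated genes at 2.64 in KARPAS-422, and with arrays at equal medians the sign turns for MHC class I and heat shock proteins in WSU-DLCL2 and SU-DHL-10, adhesion in WSU-DLCL2, DNA replication in DB and B cell identity in OCI-LY-19.

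The lines were next compared for shared responses. ABAT, which breaks down the transmitter GABA, rose in 9 of 10 lines, from 0.56 in SU-DHL-4 to 3.75 ± 0.15 in KARPAS-422. MSRB2, a methionine sulfoxide reductase gene, TSC22D1, the actin-severing protein gene DSTN, SMKR1, PRKAR2B, FAM229B and HLA-DOA also rose in 9 lines, and none of these 8 genes was called in Toledo. TSC22D1 reached 3.25 ± 0.08 and MSRB2 2.24 ± 0.13 in KARPAS-422, DSTN reached 2.00 ± 0.09 in SU-DHL-10, and HLA-DOA ran from 0.34 in HT to 0.86 in Pfeiffer. FABP6, FKBP1B, SH3BP5 and the lysosomal membrane gene SCARB2 rose in 8 lines. NUP155, of the nuclear pore, fell in 8 lines, most in KARPAS-422 (-0.66 ± 0.06). SLC3A2, the heavy chain of amino acid transporters (WSU-DLCL2 -1.61 ± 0.09), DTL, which controls replication licensing (Pfeiffer -0.97 ± 0.06), the prolyl hydroxylase gene P4HA1 (KARPAS-422 -1.06 ± 0.06), DONSON, GCLM, NCAPG2 and YARS1 fell in 7.

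In all, 1437 genes rose in at least 3 lines, against a mean of 640.2 and a highest value of 708 in 1000 shuffles, and 415 rose in at least 5, against 10.1 and 20. Falls were shared by at least 3 lines in 924 genes, against 444 and 495, and by at least 5 in 152, against 5.48 and 13. The permutation p was 0.001 for each, the smallest that 1000 shuffles can give. Another 3042 genes rose and 2355 fell in exactly 1 line, and 1382 rose in 1 line and fell in another. Log2 fold changes of pairs of lines correlated across genes, which are not independent replicates, at -0.01 to 0.34 (median 0.15), and pairs with Toledo had a median of 0.03. Without KARPAS-422 the genes risen in at least 5 lines numbered 243 and those fallen in at least 3 numbered 539, and without WSU-DLCL2 those fallen in at least 5 numbered 53. With arrays at equal medians 641 genes rose and 2332 fell in at least 3 lines, and 151 and 527 in at least 5.

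**Figure D3:**
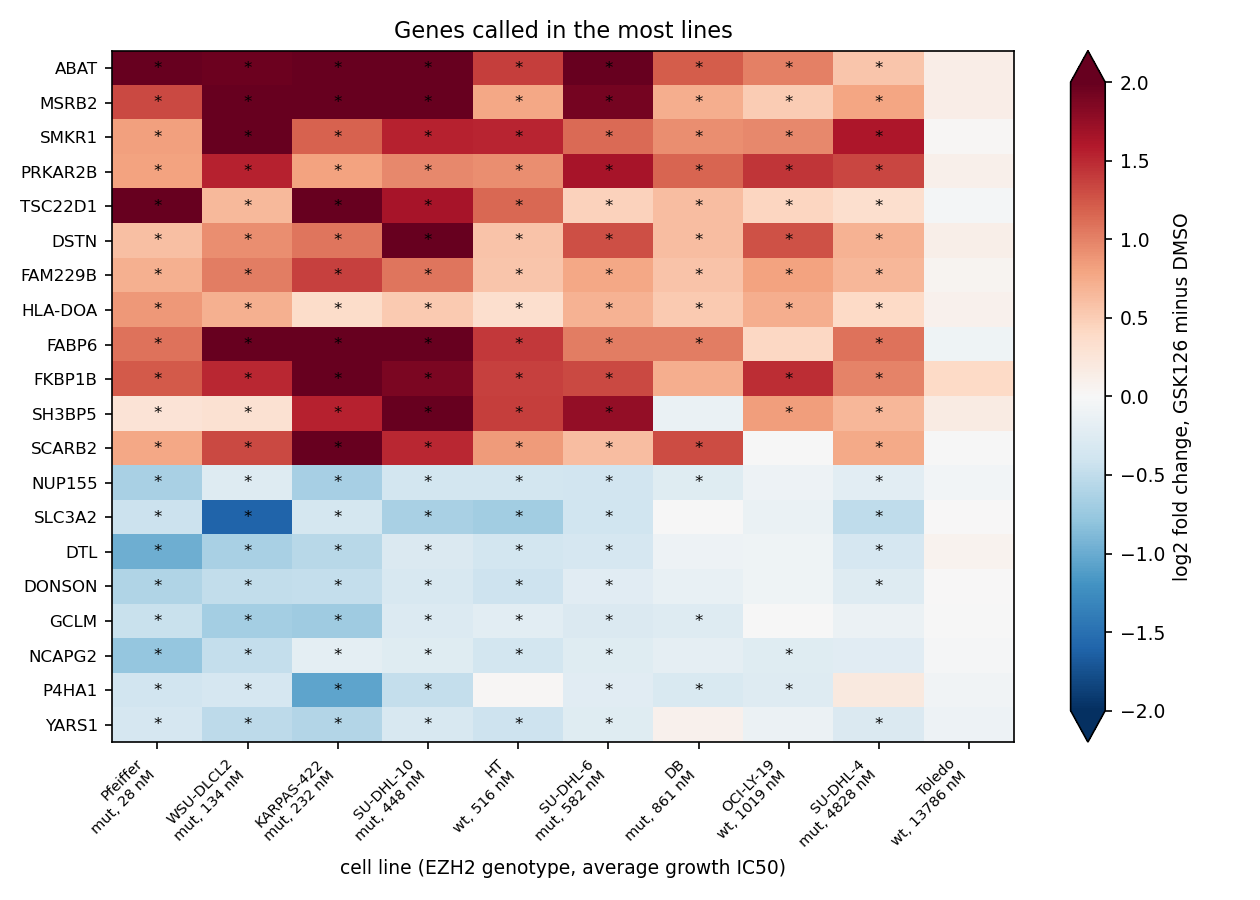
Log2 fold change (colour, from -2 to 2) of the 12 risen and 8 fallen genes called in the most lines, by line, with a star where the gene was called. ABAT and 7 other genes carry a star in 9 of 10 lines, and NUP155 in 8.

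As a mean over the 7 mutant lines, 1019 genes rose and 497 fell (limma with the line as replicate), and 88 rose and 3 fell at least 2-fold. The largest mean rises were ANXA4 at 2.08 ± 0.20, adjusted p = 0.00169, ABAT at 2.07 ± 0.29, adjusted p = 0.00299, SRGN at 1.98 ± 0.43, adjusted p = 0.0157, FABP6 at 1.78 ± 0.31, and TCL1A at 1.69 ± 0.45, adjusted p = 0.0355. They were followed by SESN3, a sestrin gene, at 1.64 ± 0.25, MSRB2 at 1.60 ± 0.18, the calcium-binding S100A4 at 1.57 ± 0.31, UMODL1 at 1.57 ± 0.29, FKBP1B at 1.47 ± 0.20, SEPTIN8 at 1.41 ± 0.30 and CIB2 at 1.40 ± 0.24. The largest mean falls were LTA at -1.15 ± 0.32, adjusted p = 0.0404, INHBE at -1.14 ± 0.31, LRRTM4-AS1 at -1.10 ± 0.32, DNAH6 at -0.67 ± 0.16, and SHISA8 at -0.63 ± 0.17. They were followed by NAB2, a repressor of early response factors, at -0.61 ± 0.13, CDC45 at -0.61 ± 0.11, adjusted p = 0.008, LARP1B at -0.61 ± 0.11, the checkpoint kinase gene CHEK1 at -0.61 ± 0.15, the glutamine transporter gene SLC1A5 at -0.60 ± 0.12, LINC00662 at -0.60 ± 0.16 and ZFP69B at -0.58 ± 0.13. EZH2 fell by a mean of -0.25 ± 0.07, adjusted p = 0.0372 and SUZ12 at -0.15 ± 0.04, adjusted p = 0.0445, while EPOP (0.51 ± 0.09, adjusted p = 0.00825) and JARID2 (0.43 ± 0.11, adjusted p = 0.0304) rose. TXNIP rose by 1.09 ± 0.22, adjusted p = 0.012, and TNFRSF21 did not pass the test (0.84 ± 0.32, adjusted p = 0.113).

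**Figure D4:**
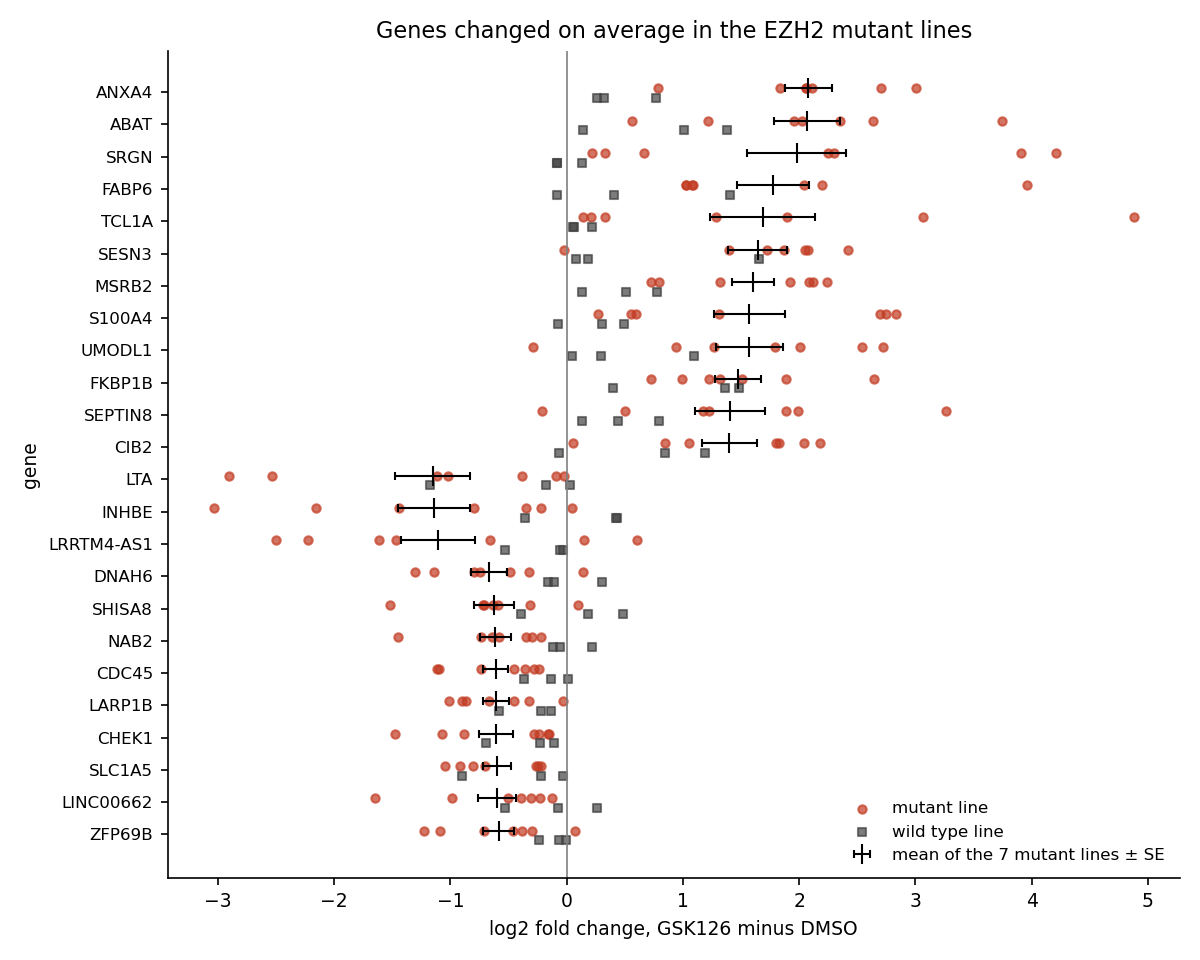
Log2 fold change of the named genes in each of the 7 mutant lines (dots) with the mean and its standard error (bar). ANXA4 has a mean of 2.08 ± 0.20 and LTA of -1.15 ± 0.32.

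DNA replication genes fell on average in the mutant lines, 16 of 29 (28 fallen adjusted over the list alone, median -0.30, camera adjusted p = 5.94e-17, adjusted p = 0.565 with an estimated correlation), E2F1 at -0.48 ± 0.08 and CDC6 at -0.46 ± 0.11. Of 30 mitotic genes 7 fell (18 fallen adjusted over the list alone, median -0.19, camera adjusted p = 2.59e-12, adjusted p = 0.565 with an estimated correlation), AURKB at -0.44 ± 0.10. MHC class I had 5 of 17 risen (10 risen adjusted over the list alone, median 0.28, camera adjusted p = 0.000244, adjusted p = 0.565 with an estimated correlation), NLRC5 by 0.75 ± 0.21 and HLA-B by 0.72 ± 0.15. Of 37 interferon-stimulated genes 5 rose (5 risen adjusted over the list alone, median 0.57, camera adjusted p = 0.000303, adjusted p = 0.863 with an estimated correlation), IFI6 by 1.24 ± 0.19. The interferon call was lost without KARPAS-422 (adjusted p = 0.0756). Adhesion genes had 7 of 30 risen (7 risen adjusted over the list alone, median 0.18, camera adjusted p = 0.00818, adjusted p = 0.565 with an estimated correlation), the actin-capping gene CAPG by 1.18 ± 0.18. None of these 5 lists kept its call with an estimated correlation. The fry test found movement one way for DNA replication, MHC class I and adhesion (adjusted p = 0.0265 for each) but not for mitosis (0.0715) or interferon (0.255). Single members of other lists also passed the test. PHC1 (0.62 ± 0.08), CBX7 (0.74 ± 0.19) and PCGF2 (0.65 ± 0.17) of PRC1 rose, as did HOXC6 (0.69 ± 0.18), HOXC4 (0.49 ± 0.10) and HOXB3 (0.48 ± 0.12). The B cell regulator genes PRDM1 (0.99 ± 0.28), BACH2 (1.11 ± 0.30), the sestrin gene SESN1 (1.31 ± 0.22) and the death ligand gene TNFSF10 (0.99 ± 0.20) rose too.

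The mutant mean rested on single lines to some degree. Without 1 line the count of 1516 became 757 without Pfeiffer, 728 without WSU-DLCL2, 771 without SU-DHL-10 and 901 without SU-DHL-6, and TCL1A, LTA, INHBE, LRRTM4-AS1, SHISA8, CHEK1, DNAH6, LINC00662 and ZFP69B each lost the call without at least 1 line. With the mean of all probe sets of a gene DNAH6 turned to 0.02, and NAB2, LRRTM4-AS1 and LINC00662 lost the call. With weights per line the count was 758. With arrays at equal medians 622 genes rose and 2084 fell.

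As a mean over the wild type lines HT, OCI-LY-19 and Toledo, limma called 0 genes. At an unadjusted p under 0.05 there were 602, against 760.55 expected by chance. DNA replication (median -0.12, camera adjusted p = 1.56e-05, adjusted p = 0.81 with an estimated correlation) and mitosis (median -0.08, camera adjusted p = 0.000439, adjusted p = 0.81 with an estimated correlation) lists shifted down. Glycolysis (median -0.07, camera adjusted p = 0.00867, adjusted p = 0.81 with an estimated correlation) and apoptosis (median -0.05, camera adjusted p = 0.0354, adjusted p = 0.81 with an estimated correlation) lists shifted down too, with 0 members called over all genes. For mutant minus wild type, from the same fit, limma called 0 genes (598 at an unadjusted p under 0.05), and weights per line called 1. As lists, DNA replication (median -0.16, camera adjusted p = 2.3e-05, adjusted p = 0.987 with an estimated correlation) and mitosis (median -0.11, camera adjusted p = 0.00131, adjusted p = 0.987 with an estimated correlation) fell more in mutant lines by camera. MHC class I (median 0.25, camera adjusted p = 0.00333, adjusted p = 0.987 with an estimated correlation) and interferon-stimulated genes (median 0.39, camera adjusted p = 0.0103, adjusted p = 0.987 with an estimated correlation) rose more. By fry none of the 4 moved one way (adjusted p = 0.940 for each). Mitosis lost its call without Pfeiffer (adjusted p = 0.271), MHC class I without KARPAS-422 (0.0585), and interferon without KARPAS-422 (0.925) or OCI-LY-19 (0.0922). Mutant lines had a mean of 1459 ± 859 risen genes (SD, n = 7) against 427 ± 482 (SD, n = 3) in wild type lines, a difference that did not pass an exact permutation test over 120 splits (p = 0.0833). Fallen genes numbered 1039 ± 826 against 176 ± 245 (exact p = 0.0917).

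The labels state that the lines differed in their sensitivity to the drug, and the transcriptional response was set against it. Lines with a lower growth IC50 changed more genes: Pfeiffer, WSU-DLCL2 and KARPAS-422 had the most, Toledo the fewest, and HT, a wild type line of 516 nM, lay beside the mutant SU-DHL-6 of 582 nM. Against log10 of the growth IC50, the number of risen genes had r = -0.862 (permutation p = 0.00015, adjusted over 3 measures 0.00045) and rho = -0.939 (p = 0.00025, adjusted 0.00033). For fallen genes r was -0.776 (p = 0.00545, adjusted 0.00818) and rho -0.927 (p = 0.00033, adjusted 0.00033), and for the SD of all log2 fold changes r was -0.729 (p = 0.0161, adjusted 0.0161) and rho -0.939 (p = 0.00028, adjusted 0.00033). Without Toledo and Pfeiffer, the lines farthest from the median, r was -0.842, -0.829 and -0.776. Among the 7 mutant lines r was -0.846 for risen genes (exact permutation p = 0.00734, adjusted 0.0220) and -0.765 for fallen ones (0.0359, adjusted 0.0539), and for the SD -0.685 (0.0849, adjusted 0.0849). The rho values there were -0.893 (exact p = 0.0123, adjusted 0.0238), -0.857 and -0.857 (0.0238 for both, adjusted 0.0238). Centred within the 3 R tags, the largest of which holds 5 lines, r was -0.880 (exact p = 0.00347 over 1440 orders), -0.801 (0.0389) and -0.745 (0.104).

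**Figure D5:**
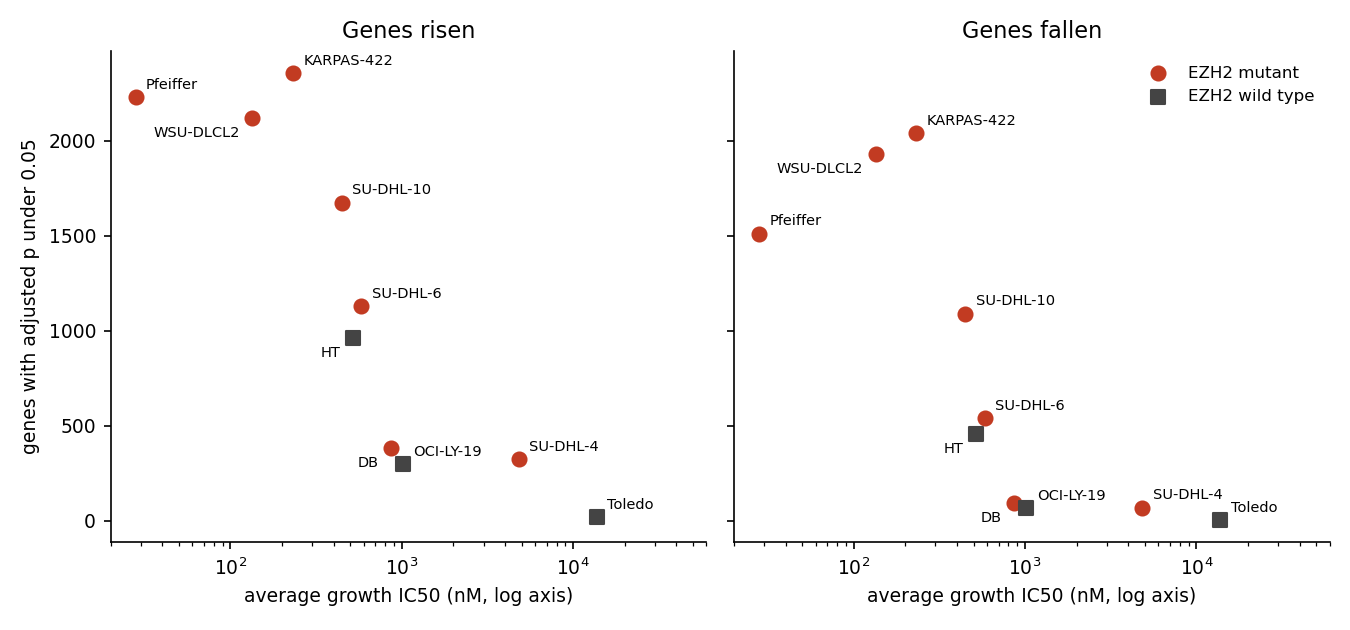
Number of called genes risen (left) and fallen (right) in each line against the average growth IC50 in nM on a log axis, with circles for mutant and squares for wild type lines. Risen genes decline from 2228 in Pfeiffer at 28 nM to 21 in Toledo at 13786 nM, with r = -0.862.

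Gene by gene, 1 response followed the growth IC50. EEF2KMT, which methylates a translation elongation factor, changed by 0.71 ± 0.09 per 10-fold higher IC50 (adjusted p = 0.0268), running from -0.70 in Pfeiffer to 1.28 in Toledo, and was called in no single line. The count of 1, with 1631 genes at an unadjusted p under 0.05, became 0 without Pfeiffer, SU-DHL-10, HT, SU-DHL-6, DB, SU-DHL-4 or Toledo and 2 without KARPAS-422 or OCI-LY-19. TXNIP rose less in lines with a higher IC50 by its estimate (slope -0.89 ± 0.13, adjusted p = 0.0648), which did not pass the test. The more sensitive lines had the larger falls of DNA replication (median 0.24, camera adjusted p = 1.55e-20, adjusted p = 0.327 with an estimated correlation) and mitotic genes (median 0.18, camera adjusted p = 4.96e-17, adjusted p = 0.327 with an estimated correlation), where medians are slopes per 10-fold IC50. They had the larger rises of adhesion (median -0.17, camera adjusted p = 0.00195, adjusted p = 0.0844 with an estimated correlation), interferon-stimulated (median -0.28, camera adjusted p = 0.00732, adjusted p = 0.782 with an estimated correlation) and B cell identity genes (median -0.10, camera adjusted p = 0.027, adjusted p = 0.744 with an estimated correlation). By fry, only adhesion moved one way (adjusted p = 0.000657).

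Under DMSO the genotypes differed in 8 genes, 4 higher and 4 lower in mutant lines. PLEK, which encodes the signalling protein pleckstrin, averaged 11.55 in mutant and 6.53 in wild type lines on the log2 scale, a difference of 5.02 ± 0.68 (limma, adjusted p = 0.0402, n = 7 and 3). SOBP was higher by 4.34 ± 0.58 (adjusted p = 0.0386), the pseudokinase gene TRIB2 by 4.33 ± 0.40 (adjusted p = 0.0038) and ANKRD44 by 2.11 ± 0.26 (adjusted p = 0.0206). IGLL1, a surrogate light chain gene of precursor B cells, was at 6.51 in mutant and 13.57 in wild type lines, a difference of -7.06 ± 0.49 (adjusted p = 0.0005). MID1IP1 (-4.85 ± 0.68, adjusted p = 0.0428), TGIF1 (-4.31 ± 0.52, adjusted p = 0.0206) and APOL3 (-3.42 ± 0.37, adjusted p = 0.0101) were lower too. The APOL3 level of 4.63 in mutant lines lies near the background, so the size of its difference depends on the pseudocount. By camera, germinal centre (median 1.41, camera adjusted p = 0.000503, adjusted p = 0.735 with an estimated correlation) and MHC class II (median 1.49, camera adjusted p = 0.011, adjusted p = 0.735 with an estimated correlation) genes were higher in mutant lines, where medians are differences of log2 levels. So were NF-kB (median 0.58, camera adjusted p = 0.0237, adjusted p = 0.735 with an estimated correlation) and cholesterol synthesis (median 0.16, camera adjusted p = 0.0237, adjusted p = 0.735 with an estimated correlation) genes. The count of 8, with 1182 at an unadjusted p under 0.05, became 152 without HT, 13 without Pfeiffer, 5 without Toledo, 4 without OCI-LY-19 and 3 without WSU-DLCL2, SU-DHL-10, DB or SU-DHL-4. With the R tag as a block it was 4, where PLEK, SOBP, ANKRD44, TGIF1 and MID1IP1 lost their calls. SOBP also lost its call with the mean of all probe sets (1.47), MID1IP1 with a pseudocount of 1 and without a filter on dim genes, and PLEK with 4 times the pseudocount.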

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

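The tests of replicate spread, R tags and slower growth, of array scaling, of bright genes by a line's own signal, of other cell types and of pairs of lines with opposite list calls were chosen only after the results they bear on had been seen.

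Of 82 sets of 7 mutant lines, 8 had 1 line far from the others by Dixon's test, which by chance marks about 1 set in 20. The value given is the gap to the nearest line as a share of the range. FABP6 rose by 3.96 in SU-DHL-10 against a median of 1.08 in the other mutant lines (share 0.601), and SLC3A2 fell to -1.61 in WSU-DLCL2 against -0.41 (0.594). SESN3 stood at -0.03 in SU-DHL-4 against 1.96 (0.582) and NAB2 at -1.45 in KARPAS-422 against -0.46 (0.580). The DMSO level of APOL3 was 4.93 in WSU-DLCL2 against 4.58 (0.678), a small difference on the log2 scale between levels near the background. The medians of interferon-stimulated genes (2.64 against 0.14, share 0.878) and MHC class I genes (1.01 against 0.17, share 0.745) stood apart in KARPAS-422, and that of NF-kB targets in WSU-DLCL2 (-0.68 against -0.04, share 0.578).

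Each of 4 lists was called upwards in 1 line and downwards in another, and camera then tested the difference of the 2 lines, adjusted over these 4 tests. NF-kB targets differed by a median of 0.80 between Pfeiffer and WSU-DLCL2 (adjusted p = 2.2e-11, and 3.88e-05 with an estimated correlation), and cholesterol synthesis genes by 0.58 between WSU-DLCL2 and Pfeiffer (1.67e-14 and 1.2e-05). MYC targets differed by 0.31 between DB and KARPAS-422 (7.38e-09 and 0.00123) and apoptosis regulators by 0.33 between Pfeiffer and HT (8.36e-05 and 0.000436). Of the 4 upward calls 3 were lost with an estimated correlation, those of NF-kB targets (adjusted p = 0.118) and apoptosis regulators (0.0519) in Pfeiffer and of MYC targets in DB (0.176). The same 3 were lost with quantile normalization (0.0554, 0.0561 and 0.247), which also ended the downward call of apoptosis regulators in HT (0.0767). Line pairs were picked for opposite calls, so these p-values are too small. Of 43 named genes (several lines, mutant mean or always), 0 moved one way in all mutant and the other in all wild type lines. Those called in 8 or 9 lines could not. Among 7954 tested probe sets with no symbol or several, unused above, 44 rose and 9 fell in 5 or more lines. In 100 shuffles, which ignore shared spread too, a mean of 0.35 and at most 2 rose.

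Lines with a lower growth IC50 changed more genes. Unequal replicate spread is argued against: the SD of log2 fold changes after subtracting replicate variance still had rho = -0.939 (permutation p = 0.00024, adjusted over 5 relations 0.0012) and r = -0.821 (p = 0.00307, adjusted 0.0154) with log10 IC50, r without Toledo and Pfeiffer being -0.830. The R tags as sole cause are argued against by r = -0.880 for risen genes centred within tags (exact p = 0.00347). Slower growth of sensitive lines remains a candidate explanation, since the median of 59 mitotic and replication genes followed the IC50 with rho = 0.806 (permutation p = 0.00724, adjusted 0.0181) and r = 0.794 (p = 0.0062, adjusted 0.0155), 0.504 without Toledo and Pfeiffer and 0.879 within tags. A difference between lines in their dependence on EZH2 also stays open and was not tested.

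Genes changed at least 2-fold mostly rose, 3134 against 466 over the 10 lines (87.1%). Array scaling as the whole cause is argued against: with arrays at equal medians 10 of 10 lines still had more such rises than falls, although the share dropped to 69.7% and WSU-DLCL2 was nearly even at 317 against 310. Compression of falls near the background stays open: rises were 79.8% of 2-fold changes among genes in the top tertile of the other lines' DMSO signal, past the bound set in advance, but such genes can be dim in the line itself, and in the top tertile of its own DMSO signal, a choice that favours falls, rises were 52.2% (140 against 128), with 25 against 32 in Pfeiffer, 27 against 61 in WSU-DLCL2 and 71 against 26 in KARPAS-422. It also stays open that genes low in a line before treatment may rise in it, since 10 of 10 lines had a negative correlation across genes, which are not independent, of the relative DMSO level of replicate 1 with the response of replicate 2 (-0.208 to -0.031). Loss of repression by EZH2 is 1 possible explanation of such a pattern, and histone methylation was not measured here.

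The rise of interferon-stimulated genes in KARPAS-422 was not that of a single array, as 33 of 37 had both GSK126 arrays above both DMSO arrays. T and NK or myeloid cells as its sole source are argued against, since their 15 and 10 tested markers had median log2 fold changes of -0.37 (SD 0.58) and -0.18 (SD 0.60), more than 2 SD below the 2.64 of the interferon genes, while erythroid or endothelial cells (-0.067 over only 6 markers) and stromal or epithelial cells (0.69 over 10 markers, 2 of them risen, fry adjusted p = 0.000163, camera adjusted p = 0.321) stay open. The genes were not low before treatment: their DMSO level in KARPAS-422 lay 1.10 above the other lines' mean, and OCI-LY-19, at 1.34, had a response of 0.03. Over the 10 lines DMSO level and response had rho = 0.236 (permutation p = 0.513, adjusted 0.641) and r = 0.538 (p = 0.158, adjusted 0.197), 0.454 without OCI-LY-19 and KARPAS-422 and 0.484 within R tags. A KARPAS-422 response through interferon signalling is a possible explanation that was not tested, and the 2 treated cultures might share an exposure that no label records.

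Other assignments of the lines were fitted to see whether chance gives as many genes. For the mutant mean, 1 of 64 sign patterns, the real one, gave 1516 genes and the others at most 0. That is the smallest share that 64 patterns can give. It lies under 0.05 and argues against chance signs. It cannot tell a response to the drug from a shift common to all treated arrays. For the genotype difference in response the real count was 0, which any split reaches (100 of 100, the highest other 5), so the splits decide nothing there. For the DMSO levels, 3 of 100 splits gave at least the real count of 8, a share under 0.05, but the split that sets Pfeiffer, OCI-LY-19 and Toledo against the rest gave 88, which points to a structure of the lines other than genotype. For the slope on the growth IC50, 3 of 100 orders gave at least the real count of 1, and the highest other order gave 11.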

How the results depend on the processing

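All alternatives but equal medians, added later, were planned. In total 326 values that answer a comparison stayed within 1.5 times the main count or on the same side of the test. Another 104 counts moved further and 1 correlation fell below its threshold. Counts add risen to fallen genes, so lines whose balance turned count as stayed, as does 0 kept at 0. Of the values of single genes and lists, where a list's direction is that of camera, 1305 kept direction and call and 236 kept direction and lost the call. The medians of 7 lists changed sign with arrays at equal medians. In direction 2 genes turned: CCDC32 in Toledo to 0.016 and DNAH6 in the mutant mean to 0.022, both with the mean of all probe sets, and the cause was not tested. Background limits dim genes: probe sets under the array median on nearly all arrays were not tested, and the pseudocount shrinks changes just above it.

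A required 2-fold change lowered the counts by construction, to 576 genes in Pfeiffer, 653 in WSU-DLCL2, 955 in KARPAS-422, 620 in SU-DHL-10, 173 in HT, 335 in SU-DHL-6, 118 in DB, 90 in OCI-LY-19, 65 in SU-DHL-4, 15 in Toledo and 91 in the mutant mean. The genes risen in at least 3 and 5 lines then numbered 222 and 33, and those fallen 6 and 1. Lines fitted alone, with fewer arrays behind the variance, gave 1600 in SU-DHL-10, 374 in SU-DHL-6, 275 in DB, 138 in OCI-LY-19, 104 in SU-DHL-4 and 0 in Toledo. For the settings that follow the cause was not tested. Arrays at equal medians gave 848 genes in HT, 164 in OCI-LY-19, 191 in SU-DHL-4 and 2706 in the mutant mean, 641 and 151 genes risen and 2332 and 527 fallen in at least 3 and 5 lines, and 11 called lists in OCI-LY-19 and 9 in Toledo. Toledo had 13 genes with 4 times the pseudocount and 12 with the mean of all probe sets. Weights per line gave 758 genes for the mutant mean and 1 for the genotype difference. The slope on the growth IC50 had 2 genes with 4 times the pseudocount, quantile normalization or the mean of all probe sets, and 0 without a filter on dim genes. The R tag as a block gave 4 genes under DMSO, 3 of them among the 8 of the main model. With a pseudocount of 1 the SD of log2 fold changes had r = -0.639 with the growth IC50 (permutation p = 0.0508). Camera with an estimated correlation called 0 lists in SU-DHL-10, 1 in SU-DHL-6, 4 in DB and 0 each in Toledo, the mutant mean and the genotype difference. With quantile normalization it called 5 in SU-DHL-10, 3 in SU-DHL-6, 6 in SU-DHL-4 and 0 in Toledo.

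The replicate numbers were no sign of pairing: deviations of same-numbered arrays correlated at -0.045 to 0.069, with 0 of 10 lines over 0.1. With a replicate block Toledo had 16 genes, and no other line's count moved by over 1.5 times.

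Leaving out 1 array, where the lone array of an arm is assumed to vary like the other groups, gave 2718 to 2821 genes in Pfeiffer, 2849 to 3164 in WSU-DLCL2, 3355 to 3591 in KARPAS-422, 1862 to 2305 in SU-DHL-10, 772 to 860 in HT, 921 to 1269 in SU-DHL-6, 268 to 313 in DB, 196 to 272 in OCI-LY-19, 171 to 359 in SU-DHL-4 and 19 to 48 in Toledo. Leaving out 1 line gave 728 to 1574 genes for the mutant mean, 0 to 0 for the wild type mean and for the genotype difference, 0 to 2 for the slope and 3 to 152 under DMSO. Genes risen in at least 3 lines then numbered 1047 to 1435 and in at least 5 lines 243 to 415, and fallen genes 539 to 924 and 53 to 152. Called lists numbered 5 to 8 for the mutant mean and 2 to 6 for the genotype difference. Against the growth IC50, risen genes had r from -0.892 to -0.836 and rho from -0.967 to -0.917, fallen genes r from -0.817 to -0.748 and rho from -0.950 to -0.900, and the SD r from -0.824 to -0.689 and rho from -0.967 to -0.917.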

Other observations

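Cyclin-dependent kinase inhibitors and p53 targets were called by camera in none of the lines. By fry the kinase inhibitors moved up in KARPAS-422 (adjusted p = 0.000976) and SU-DHL-6 (0.00867) and down in SU-DHL-10 (0.000677) and OCI-LY-19 (0.0166). By fry p53 targets moved up in Pfeiffer (5.06e-07), KARPAS-422 (4.97e-06), SU-DHL-10 (0.0205), HT (0.00468) and SU-DHL-6 (2.03e-05), though their medians in Pfeiffer and SU-DHL-10 were -0.049 and -0.074. CDKN1B, which encodes p27, rose in Pfeiffer (0.35 ± 0.09), KARPAS-422 (0.49 ± 0.09) and SU-DHL-6 (0.60 ± 0.09) and fell in WSU-DLCL2 (-0.43 ± 0.09), SU-DHL-10 (-0.32 ± 0.09) and HT (-0.32 ± 0.09), differences between lines that were not tested. CDKN1A, which encodes p21, rose in WSU-DLCL2 (0.73 ± 0.27) and KARPAS-422 (1.03 ± 0.27), and CDKN2D fell in 4 lines, most in SU-DHL-10 (-0.97 ± 0.17). Among p53 targets SESN1, a stress-induced sestrin gene, rose in 7 lines, up to 2.55 ± 0.19 in WSU-DLCL2, and GADD45A rose in KARPAS-422 (2.87 ± 0.12) and 3 other lines and fell in WSU-DLCL2 (-0.44 ± 0.12). The death receptor gene FAS rose in Pfeiffer (1.53 ± 0.22) and SU-DHL-6 (1.10 ± 0.22) and fell in WSU-DLCL2 (-2.05 ± 0.22). DDB2, of nucleotide excision repair, fell in the mutant mean (-0.38 ± 0.07).

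Developmental transcription factor genes, many of them known Polycomb targets, moved up by fry in Pfeiffer (adjusted p = 0.001), HT (0.00468), OCI-LY-19 (0.0158) and SU-DHL-10 (0.0232), with no camera call. LHX2 rose in Pfeiffer (1.85 ± 0.34), HT (1.45 ± 0.34) and OCI-LY-19 (1.30 ± 0.34), ZIC2 in SU-DHL-10 (1.90 ± 0.30) and WSU-DLCL2 (1.04 ± 0.30), and MEIS1 in KARPAS-422 (1.56 ± 0.26) and WSU-DLCL2 (0.90 ± 0.26). SOX9 rose in KARPAS-422 (2.06 ± 0.31) and DB (1.32 ± 0.31) and fell in WSU-DLCL2 (-0.84 ± 0.31), and GATA6 (-1.48 ± 0.54) and GATA3 (-1.31 ± 0.44) fell in KARPAS-422. Of 27 tested, 0 passed the test in the mutant mean. Other members of lists that did so were IL16 (0.76 ± 0.15), IL15 (0.67 ± 0.18), S100A10 (0.94 ± 0.18), ANXA2 (0.65 ± 0.14) and BAG3 (0.75 ± 0.16), which rose, and PIK3CD (-0.47 ± 0.06), RELB (-0.40 ± 0.09), NSD2 (-0.40 ± 0.08), PSAT1 (-0.46 ± 0.11) and DNMT1 (-0.26 ± 0.07), which fell. The genes of these 2 paragraphs were chosen after their values were seen.

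Neither of the tests given next was chosen after its result was seen. Lines with a larger fall of replication genes might also have a larger fall of EZH2 mRNA, itself a gene of dividing cells. Over the 10 lines the median of the replication list and EZH2 had rho = 0.746 (permutation p = 0.0182, adjusted over 5 relations 0.0303) and r = 0.726 (p = 0.0179, adjusted 0.0299), and 0.731 centred within R tags. Without Pfeiffer and OCI-LY-19, the lines farthest from the median of EZH2, r was 0.381, so the linear relation leans in part on those lines. No rho or p-value was computed without them. Genes that rose in at least 5 lines could have been mostly dim ones, where scatter is widest, but their median DMSO level of 9.29 lay at the 58.0th percentile of tested genes (median 8.54). Genes that fell in at least 5 lines lay at the 87.9th percentile.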
